A study of Homo sapiens with 8 samples.

How the data were processed

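The series measured RNA in HEK 293T cells, a human embryonic kidney line, and in the microvesicles these cells shed into their medium. Per the labels' protocols, cells were transfected either with the TRACE pair of constructs, in which GFP is joined to YTHDF1 and a GFP-binding protein to CD9, or with a control pair that lacks YTHDF1. YTHDF1 is a reader of N6-methyladenosine in messenger RNA and CD9 is a tetraspanin of vesicle membranes. The medium held exosome-depleted serum and RNase A. Microvesicles were collected by serial ultracentrifugation with a 0.8 µm filtration step, and libraries were made from total RNA with SMART-Seq2 and Nextera, a kit that does not mark the strand, per the labels' protocols.

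The deposited values are whole-number counts of reads per gene feature. Per the file headers, the authors counted with featureCounts 1.6.4 in single-read mode, without multi-mapping reads, against GENCODE release 19, with the strand setting at 2 (reads on the strand opposite to the feature). Per the submitters' processing notes, reads were aligned with STAR to hg19; the version of STAR is not given in the sources used here. Because the kit does not mark strand, a feature and its antisense partner cannot be told apart, and reads of the other orientation were not counted. Each library has 2 columns, named R1 and R2, whose meaning the sources used here do not state; they were added. If they are mates of one fragment, they lie on opposite strands, so the strand setting counts at most 1 of them on a given feature. A fragment could then count more than once only where features lie on both strands. All 16 count columns were used, and 0 columns of per-sample values were left out. Of 63568 features, 55665 had a current symbol. All 1190053 counts lay on the 5363 features of chromosome 1, of which 4024 had a count and 5178 a current symbol; the count outside chromosome 1 was 0.

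The 8 libraries form 4 groups of 2: cell lysates and microvesicles of construct cultures (replicates II and III) and of control cultures (replicates I and II). The labels call them separate samples without saying whether cultures were separate, so p-values measure the spread between these libraries, which may be technical. For single features that spread was taken over all 4 groups together. The series text says that microvesicles and lysate come from the same sample, so the numeral was taken to pair them within a construct. In a check over 1113 features, the deviations of paired libraries from their group means had a correlation of -0.0318 in construct and 0.0215 in control cultures.

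Differential abundance was tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in 1 model of 4 groups over 8 libraries, with Benjamini-Hochberg adjustment at 0.05 over the 1113 features tested. The model had 4 residual degrees of freedom, a prior of 6.12 and a common biological coefficient of variation of 0.665. Because the spread of a feature was shared over the 4 groups, p-values between microvesicles draw on the closer cell replicates and may be too small. Those between cells may be too large. Standard errors are the log2 fold change divided by the square root of the F statistic. The 5 contrasts, the rule for named features, 31 gene lists and 63 alternatives were fixed before the data were examined; 31 alternatives were added after seeing the data. The rule took, per contrast and direction, the 10 largest changes among features past the threshold with a mean of at least 10 CPM in the higher group and no overlap between groups; clone-type names and pseudogenes were counted and not named. Where fewer than 5 features passed, the 10 smallest p were named as not passing. Beside these, a feature is named where a list or a test needed it. Some features that the rule or a test took are not reported here. Lists were tested with limma 3.58.1 (camera, preset correlation 0.01, at least 3 tested members). The alternatives were other scalings, other filters, each library left out, DESeq2 1.42.0, limma-voom with quality weights, the compared libraries alone, and the replicate block; those added were each column alone, the 2 most abundant features left out, libraries thinned to 30552 counts after leaving out those 2, list members by position, and the features of the main fit kept without each cell library or with only the libraries compared. Values were computed with R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

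The steps were tested on simulated data of 1113 features with 200 changed. For construct against control microvesicles, 4% of 4-fold, 64% of 16-fold and 88% of 64-fold changes were called, and 0.438% of unchanged features. For the cells these were 18%, 78%, 92% and 0.438%. Within construct cultures 4%, 48% and 94% were called, with 0.438% of unchanged features. Within control cultures they were 4%, 70% and 100%, with 0.767% of unchanged features. No simulation of the interaction was run. Counts were drawn with the spread estimated over all 4 groups together, so these rates may not hold for microvesicle libraries, whose replicates were less close.

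A floor of 3 counts corresponded to between 13.3 and 83.6 CPM per library, and folds against a group at 0 are lower bounds against the mean of its libraries' floors. Intervals of shares are 95% Clopper-Pearson. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Coordinates are those of the file, on hg19: all 5178 chromosome 1 features that match the GENCODE release lifted to GRCh37 overlap their own gene there. The RefSeq table held here is on the GRCh38 assembly; it served for names and for the test of labels described with the results.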

Results

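TRACE-seq was designed to read out, from RNA in shed vesicles, what a YTHDF1 fusion binds inside the cell. The data are 8 RNA-seq libraries of HEK 293T cultures, 2 each of construct cell lysates, control cell lysates, construct microvesicles and control microvesicles. The total count was 42950 and 58664 in construct cells (replicates II and III), 109099 and 163157 in control cells (I and II), 34602 and 64025 in construct microvesicles (II and III), and 238416 and 479140 in control microvesicles (I and II). Control microvesicles thus had the deepest libraries, and depth differed between the groups compared. All counts lay on chromosome 1.

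**Figure D1:**
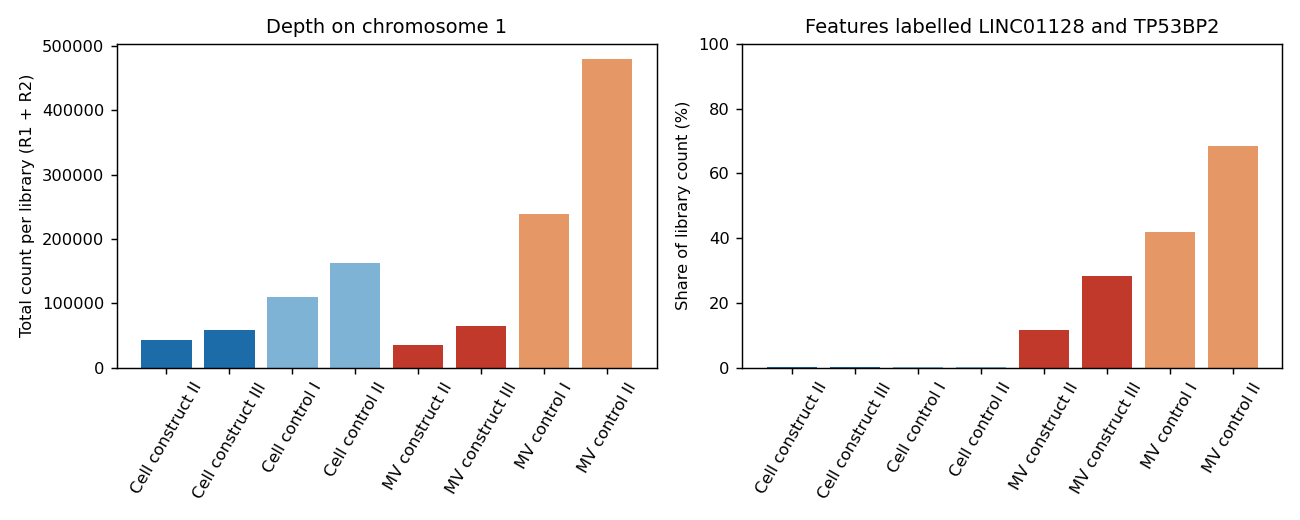
Left, total count per library (reads, both columns added). Right, percent of each library's count on the features labelled LINC01128 and TP53BP2; each bar is 1 library, coloured by group, and the share ran from 11.7% to 68.5% in microvesicles.

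The transfected genes were looked at first. YTHDF1 and CD9 had a count of 0 in every library, and so did GAPDH, ACTB and EEF1A1, which lie on other chromosomes; the construct could not be checked from these counts. Symbols on chromosome 1 did not carry the abundance known of their genes. The 139 features with a ribosomal protein symbol, pseudogenes included, had a median total count of 2, against 28 over all features with a count. Features without a count could enter the 139 but not the 28, and multi-mapping reads were not counted, so these sets are unlike. RPL11 had 7 counts in all and RPL22 had 34. At the numeric positions that the GRCh38 assembly gives ribosomal protein genes and pseudogenes, 41 features, also taken without a cut on counts, had a median of 524 counts. At least 10 counts were found on 92.7% of these 41 and on 30.2% of the 139. Symbols below therefore name counting intervals of the file, and no gene function is attached to them.

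A pair of features dominated the microvesicle libraries. The feature labelled LINC01128 (chromosome 1, 762988 to 794826, hg19) and the one labelled TP53BP2 (223967601 to 224033674) together held 19.97% ± 11.7 (SD, n = 2) of construct microvesicle counts and 55.1% ± 18.9 of control microvesicle counts. In cells they held 0.0719% ± 0.0366 and 0.0643% ± 0.0287. Over compartments the share was 37.5% ± 24.0 (SD, n = 4) against 0.0681% ± 0.0272 (n = 4), higher in 4 of 4 microvesicle libraries (exact two-sided permutation test, p = 0.0286, the smallest it allows; adjusted p = 0.0571 over 8 quantities, 3 of them chosen after seeing the data). Features at GRCh38 ribosomal protein positions held 4.51% ± 3.04 of microvesicle and 14.3% ± 2.10 of cell counts (same exact test, p = 0.0286, adjusted p = 0.0571). Features carrying ribosomal protein symbols held 0.0333% ± 0.00430 and 0.0821% ± 0.0143 (exact p = 0.0286, adjusted p = 0.0571); without the 2 dominant features this gave exact p = 0.114. Features that overlap no GRCh38 gene held 5.06% ± 1.99 of microvesicle and 1.41% ± 0.164 of cell counts (exact p = 0.0286, adjusted p = 0.0571). The 100 most abundant features (71.2% ± 10.5 against 65.9% ± 2.04, exact p = 0.371, adjusted p = 0.424), the features with a count (2546 ± 682 against 2245 ± 330, exact p = 0.457), those with at least 10 counts (exact p = 0.257) and structural and non-coding RNA lists (exact p = 0.200) did not differ beyond the spread. No adjusted value passed 0.05. These exact tests rearranged all 8 libraries freely (70 arrangements) and ignored both the pairing of microvesicles with lysate and the split by construct. A test within pairs could not reach 0.0286. Within a compartment, 2 libraries against 2 cannot give an exact p below 0.333.

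**Figure D2:**
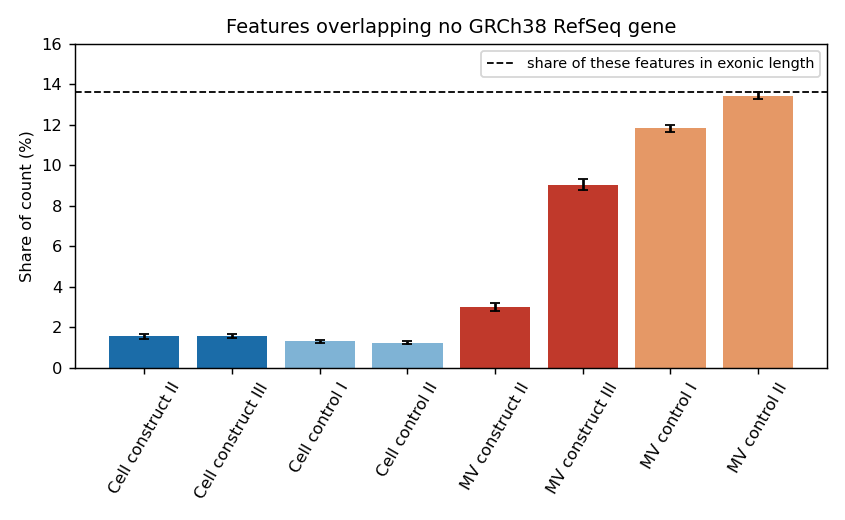
Percent of each library's count on features that overlap no GRCh38 RefSeq gene, the 2 most abundant features left out; bars are libraries and whiskers 95% Clopper-Pearson intervals (counting error only). Cell libraries lie between 1.24% and 1.55% and microvesicle libraries between 2.99% and 13.4%; the dashed line is these features' share of exonic length, 13.6%.

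Cell replicates were close and microvesicle replicates were not. Across features (which are not independent replicates), Spearman's rho between replicates was 0.890 in construct and 0.929 in control cells, but 0.379 in construct and 0.543 in control microvesicles. The chi-square per degree of freedom was 2.40 and 4.16 in cells and 22.7 and 75.1 in microvesicles with R1 and R2 added. On R1 alone it was 2.11, 3.16, 18.1 and 47.2, and on R2 alone 1.69, 3.10, 17.4 and 46.3. The statistic grows with depth where replicates differ beyond counting error, so its higher values with both columns do not show double counting. Over the 1113 features tested, construct microvesicles correlated with the mean of the cells at 0.327 and 0.278, and control microvesicles at -0.0473 and -0.0708. Over all 4024 features with a count, against summed cell counts, these were 0.549 and 0.607 in construct and 0.543 and 0.527 in control microvesicles, a smaller contrast.

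The comparison the design turns on is that of construct with control microvesicles. Of 1113 features tested, 53 were higher and 16 lower in construct microvesicles; 21 of the 69 were clone-type names or pseudogenes. The feature labelled TDRKH-AS1 (ENSG00000203288.3, chromosome 1, 151763280 to 151766878, hg19) had 1770 ± 255.7 CPM (SD, n = 2) in construct microvesicles and a count of 0 in both control libraries, at least 128-fold higher (edgeR adjusted p = 0.00355). ZBTB7B (154975127 to 154990998) had 24362 ± 15178 CPM against 40.9 ± 17.5, a log2 fold change of 9.18 ± 1.10 (SE, adjusted p = 0.00355). AGO1 (36335409 to 36395211) had 38756 ± 30498 against 181 ± 80.5 CPM, 7.73 ± 1.10 (adjusted p = 0.00541), and SF3B4 (149895209 to 149900236) had 8521 ± 3127 against 47.4 ± 33.4 CPM, 7.45 ± 1.05 (adjusted p = 0.00541). The other features named on this side were UFC1 (7.91), AURKAIP1 (7.35), TSSK3 (7.10), PPFIA4 (5.91), EPS15-AS1 (1 control count; ratio 193, interval 33.2 to 7785) and BGLAP (2 control counts; ratio 160.0, interval 43.0 to 1342). Without construct library II, the higher of the 2, the fold of means or ratio fell from 595 to 333 for ZBTB7B, from 267 to 79.9 for UFC1, from 214 to 94.9 for AGO1, from 193 to 32.2 for EPS15-AS1, from 180 to 35.6 for AURKAIP1 and from 60.5 to 15.1 for PPFIA4.

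Lower in construct microvesicles were PLA2G2A (chromosome 1, 20301925 to 20306932), with a count of 0 against 4104 ± 3255 CPM and at least 68.1-fold lower (adjusted p = 0.0162), SNRNP40, at least 32.7-fold lower (adjusted p = 0.0188), and ARHGEF19, at least 7.16-fold lower (adjusted p = 0.0245). PRKCZ fell by 5.80 ± 0.996 on the log2 scale (SE, edgeR adjusted p = 0.0134), and the log2 fold change was -6.57 for KCND3, -5.47 for GNAI3 and -5.39 for TCEANC2. Like the other features named in this contrast, PRKCZ overlaps GRCh38 genes of other names. AMIGO1 had 2 construct counts (ratio 196, interval 54.1 to 1619) and JMJD4 had 1 (ratio 97.0, interval 17.3 to 3844). Without control library II, the higher of the 2, the fold fell from 196 to 6.49 for AMIGO1 (25 counts in I and 1432 in II), from 101 to 22.9 for KCND3, from 97.0 to 60.8 for JMJD4, from 68.1 to 29.9 for PLA2G2A, from 51.8 to 30.0 for TCEANC2 and from 48.5 to 32.0 for GNAI3. With the 4 microvesicle libraries alone, and so without the spread shared with cell libraries, edgeR called 0 (128 at an unadjusted p under 0.05). It called 0 without any 1 of the 4 cell libraries, where the filter kept 1462 to 1874 features, and with the 1113 features kept it called 9 without construct cell library II or III and 16 without control cell library I or II. It called 35 without construct microvesicle library II, and without control library I or II 115 and 109, of which 72 and 74 were lower, while limma-voom with quality weights called 21 and DESeq2 141.

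**Figure D3:**
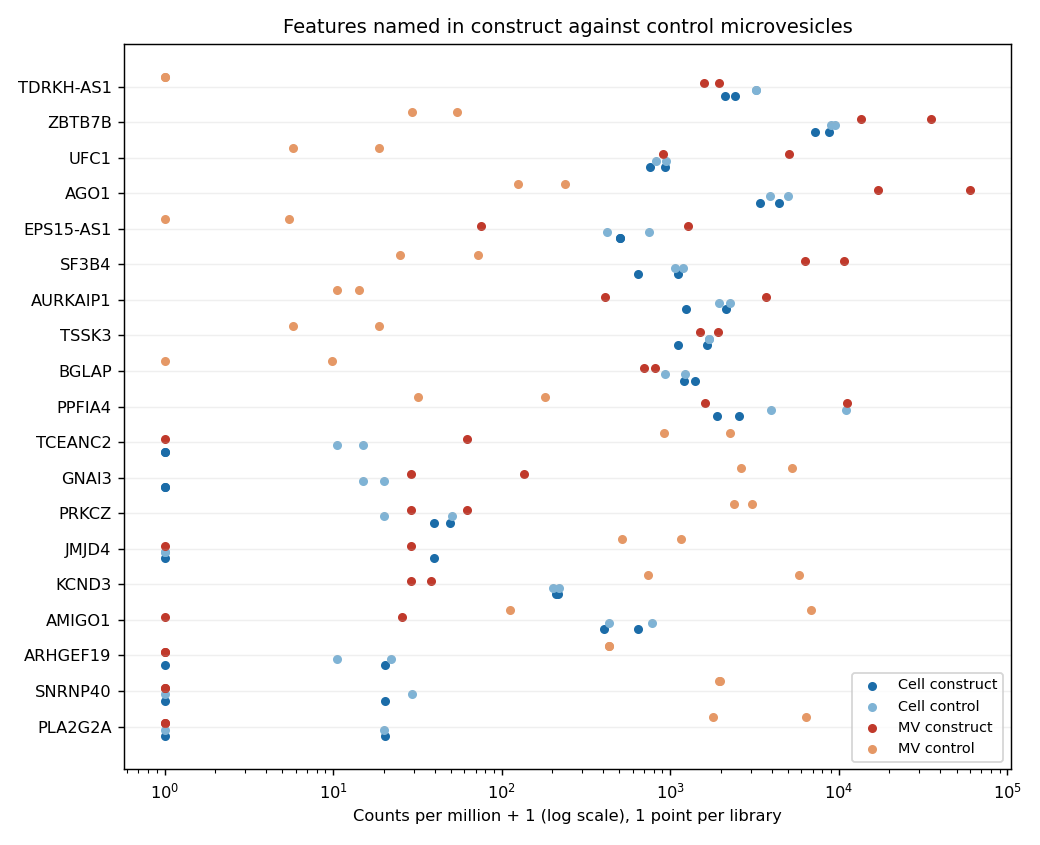
CPM plus 1 (log axis) of 19 features named in construct against control microvesicles, 1 point per library, coloured by group. The 10 called higher averaged between 0 and 181 CPM in control microvesicles.

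Construct and control cells were told apart by no feature in the main test. edgeR called 0 of 1113 features, with 10 at an unadjusted p under 0.05; DESeq2 called 0 (2 unadjusted) and limma-voom called 0 (80 unadjusted). With the 4 cell libraries alone edgeR called 0 of 628 features (97 unadjusted). It called 21 (all lower in construct cells) of 1105 when the features of the main fit were kept (117 unadjusted). The main test drew its spread from microvesicle libraries too, so its lack of calls does not show that the cells were alike. The smallest p belonged to LEFTY2, at 261 ± 70.9 CPM in construct and 1656 ± 1542 in control cells (-2.67 ± 0.98 SE), with adjusted p = 1 for it and all others named. Without control cell library II (389 counts, against 59 in I) its ratio of control to construct fell from 6.35 to 2.17. The feature ENSG00000232372.1 had -1.93 ± 0.84 and SESN2 2.11 ± 0.93. With 1 to 3 counts in construct cells, the ratio of control to construct was 7.21 for RAB13 (interval 2.32 to 36.2), 22.6 for FDPS (3.86 to 909) and 5.22 for PARK7 (1.64 to 26.5). NOTCH2, with 3 counts in control cells, had a ratio of construct to control of 7.24 (1.86 to 40.9), and 4.78 without construct cell library III. ENSG00000261250 and TARBP1 had no construct cell counts and 8 and 11 control counts, too few for a fold.

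Microvesicles were next compared with the lysates of their own cultures. In construct cultures 11 features were higher and 47 lower in microvesicles, 15 of them clone-type names or pseudogenes. PKP1 (chromosome 1, 201252580 to 201302121) had 1119 ± 1059 CPM (SD, n = 2) in microvesicles and a count of 0 in cells, at least 20.9-fold higher (adjusted p = 0.0314), and CSF3R was likewise at least 20.9-fold higher. TP53BP2 rose by 7.92 ± 1.18 on the log2 scale (SE, adjusted p = 0.0252) and NOC2L by 6.46 ± 1.14 (adjusted p = 0.0252). TCHH rose by 4.74 and CDK18 by 4.02, ERICH3 was at least 4.47-fold and TMCO4 at least 4.10-fold higher, and CD84 had 2 cell counts (ratio 22.7, interval 5.95 to 193). PARS2 (55222571 to 55230187), at 2157 ± 110 CPM in cells and 0 counts in microvesicles, was at least 35.8-fold lower (adjusted p = 0.0260). TMEM167B-DT was at least 17.2-fold, TP73 14.04-fold, SNORD59 10.0-fold, LENEP 7.65-fold, PDC-AS1 7.57-fold, SYPL2 6.04-fold, TP73-AS2 4.86-fold and NUP133-DT 4.14-fold lower, and CD53 had 1 microvesicle count (ratio 252, interval 44.8 to 10002). edgeR called 0 features with these 4 libraries alone, without any 1 cell library and without construct microvesicle library II (189, 179 to 212 and 431 at an unadjusted p under 0.05), and 123 and 102 without control microvesicle library I or II. With the 1113 features kept it called 25 with these 4 libraries alone and 0 without any 1 cell library. Without construct microvesicle library II the bound fell to 6.92 for PKP1 and 2.77 for CSF3R (75 counts in II and 12 in III). Without library III the fold fell from 90.7 to 37.2 for NOC2L, from 16.9 to 10.7 for CDK18 and from 4.47 to 1.56 for ERICH3. Scaling moved the balance, from 11 higher and 47 lower to 33 and 33 with upper-quartile factors, and library size alone left 16 calls.

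In control cultures 175 features were higher and 232 lower in microvesicles, and 83 of the 407 were clone-type names or pseudogenes. PKP1 was at least 79.9-fold higher in microvesicles (adjusted p = 0.00579), and TP53BP2 rose from 300 ± 85.2 to 351716 ± 273053 CPM (10.19 ± 1.29 SE, adjusted p = 0.00312). JMJD4 was at least 33.7-fold, CSF3R 18.5-fold, TNFRSF14-AS1 17.9-fold and PIFO 11.6-fold higher. PLA2G2A had 2 cell counts (ratio 495, interval 137 to 4088), MFAP2 had 1 (ratio 1240, interval 222 to 48983) and BRINP2 had 3 (ratio 270.3, interval 92.3 to 1312); ECHDC2 rose by 8.44 ± 2.45. Control microvesicle libraries I and II had 38 and 2156 counts of MFAP2, 6 and 1429 of BRINP2 and 10 and 3210 of ECHDC2. Without library II the fold fell from 1240 to 41.5 for MFAP2, from 270.3 to 2.18 for BRINP2, from 358 to 2.07 for ECHDC2, from 1173 to 529 for TP53BP2, from 495 to 222 for PLA2G2A, from 33.7 to 20.8 for JMJD4 and from 11.6 to 5.51 for PIFO. Without library I it fell from 79.9 to 48.4 for PKP1 and from 17.9 to 7.63 for TNFRSF14-AS1. On the lower side NENF, at 7477 ± 69.0 CPM in cells, had a count of 0 and was at least 542-fold lower (adjusted p = 0.00828). TDRKH-AS1 was at least 233-fold, OR2T29 65.7-fold, RPS27 62.1-fold, TMEM167B-DT 49.6-fold, SNORD59 45.9-fold and LENEP 34.5-fold lower. MED8 had 1 microvesicle count (ratio 1538, interval 275 to 60821), ODR4 had 2 (ratio 759, interval 210 to 6280) and AGT had 1 (ratio 547, interval 97.4 to 21671). Without construct cell library II or III edgeR called 79 and 106 features, and without control cell library I or II 42 and 32; with the 1113 features kept these were 300, 299, 99 and 84. Upper-quartile factors gave 312 higher and 188 lower, and library size alone 71 and 208.

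The interaction tested whether microvesicles differed from cells by another amount in construct than in control cultures. Of 1113 features, 19 had a higher and 1 a lower log2 ratio of microvesicles to cells in construct than in control cultures, 8 of them clone-type names or pseudogenes. A higher ratio need not be an enrichment over cells: TDRKH-AS1 had 1770 CPM in construct microvesicles and 2273 in construct cells, against 0 and 3222 in control cultures. BGLAP had 755 and 1299 against 4.44 and 1075, and SNAPIN 778 and 928 against 14.1 and 1685, while AGO1 had 38756 and 3919 against 181 and 4430. Without construct microvesicle library II the fold between microvesicles fell from 595 to 333 for ZBTB7B, from 214 to 94.9 for AGO1 and from 55.1 to 33.2 for SNAPIN. ZBTB7B had an interaction of 9.39 ± 1.27 (SE, edgeR adjusted p = 0.00838), AGO1 7.91 ± 1.31 (adjusted p = 0.0185), SF3B4 7.81 ± 1.26 (adjusted p = 0.0178), and TSSK3 7.39 ± 1.24 (adjusted p = 0.0185). TDRKH-AS1 (fitted value 11.16) and the opposite case, ENSG00000224969 (fitted value -10.09; 0 construct and 524 control microvesicle counts), had a group at 0, so their fitted values depend on the prior count. edgeR called 0 features without any 1 of the 4 cell libraries (also with the 1113 features kept), 62 without construct microvesicle library III and 10 without control microvesicle library II.

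Gene lists gave little, since most members lie off chromosome 1. By symbol, 2 lists had enough members; symbols here name counting intervals, so these tests say nothing of the gene groups themselves. The features labelled as nuclear speckle and splicing genes had 4 tested members, of which 0 changed between construct and control microvesicles (1 adjusted over the list alone; camera adjusted p = 0.885), and those labelled as membrane and secretory signal genes also had 4, of which 0 changed (3 adjusted over the list alone; adjusted p = 0.885). Neither passed in any of the 5 contrasts. Of the markers of other cell types, erythroid and fibroblast lists had 0 features on chromosome 1 and the hepatocyte list 0 tested. In control microvesicles against cells the feature labelled FLG rose by 4.27 ± 0.94 (SE, edgeR adjusted p = 0.0101) and the one labelled PTPRC fell by 2.93 ± 0.93 (adjusted p = 0.0346), 1 feature each, too few to test as lists and, taken by symbol, without bearing on cell types.

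Longer features tended to have lower fold changes between construct and control microvesicles. Spearman's rho across 1113 features, which are not independent replicates, between exonic length and log2 fold change was -0.215 for construct against control microvesicles, and -0.213 to -0.128 over the 4 single pairs of libraries. Against cells it was 0.200 in construct and 0.331 in control microvesicles, and between cells 0.0302. The first value was -0.0233 over features of at least 5 mean CPM, and 0.0132 and 0.0713 without construct microvesicle library II or III. Those last 2 fits also tested more features (1849 and 1684), so library and feature set changed together. Over the 1113 features all 4 single pairs stayed negative, so the sign was not stable across the sets of features tested.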

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

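The tests of labels, of background, of cell levels, of overlap with the calls against cells, of equal depth and of the 2 most abundant features were chosen after the data were seen, the last 2 before their own values were known. The test of the 2 most abundant features was for a time replaced, after its value was known, by one of limma-voom weights (21 calls), and then restored.

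The interaction drew attention because the change from cells to microvesicles differed between construct and control cultures in 20 features by a direct test. The log2 interactions of those named were 11.16 for TDRKH-AS1, 9.39 for ZBTB7B, 7.96 for UFC1, 7.91 for AGO1, 7.81 for SF3B4, 7.66 for AURKAIP1, 7.39 for TSSK3, 6.80 for ACAP3, 6.79 for BGLAP, 6.54 for SNAPIN and -10.09 for ENSG00000224969. Without construct microvesicle library II the fold between microvesicles fell from 595 to 333 for ZBTB7B, from 267 to 79.9 for UFC1, from 214 to 94.9 for AGO1, from 180 to 35.6 for AURKAIP1, from 55.1 to 33.2 for SNAPIN and from 32.1 to 16.01 for ACAP3.

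The first pattern is that symbols do not carry the reads of their genes. That reads and symbols share hg19 is argued against by the median count of 2 on 139 features with ribosomal protein symbols, against 28 over features with a count. This comparison is weak on its own, since the 139 hold pseudogenes and were not limited to features with a count. Reads aligned to GRCh38 and counted with an hg19 annotation may explain it. The median of 524 at GRCh38 ribosomal protein positions exceeded all 1000 circular shifts in a permutation of positions (highest 358, p = 0.000999, the smallest it can give), and 1.337% of cell counts lay outside GRCh38 gene spans against at least 13.55% after shifts (p = 0.000999). Submitters' notes name hg19, and the alignments themselves were not analysed here; no biological explanation was tested.

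The second pattern is the background in microvesicles. With the 2 most abundant features left out, features outside GRCh38 genes held 2.992% to 13.44% of microvesicle counts and at most 1.55% of cell counts. Unspliced or nuclear RNA of annotated genes is argued against as the whole cause by the lowest microvesicle share, 2.992%, which lay above every cell library. Reads in proportion to length, as genomic DNA would give, may contribute: the highest share, 13.44% in control microvesicle library II, is close to these features' 13.6% of exonic length. In that library NOC2L had 6121 and MFAP2 2156 counts, both outside GRCh38 genes, so the closeness may rest on few features. Its 100 most abundant features held 51.1% of counts, again without the 2 most abundant overall. A biological source of intergenic RNA in vesicles stays open and untested. The count outside chromosome 1 was 0, so none of these sources could be looked for on other chromosomes.

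The third pattern is the 53 features called higher in construct than in control microvesicles. The 2 most abundant features and the scaling they disturb are argued against as its cause. Of the 69 calls, 68 stayed without those 2 features. Scaling by library size alone kept 62, but these sizes still hold the 2 features, so that count cannot decide on them. At equal depth, with those 2 also left out, 47 were called again. The median log2 fold change there was 5.936 for the 50 with a value, against 5.68 over all 53. Fold changes are already scaled to library size, so thinning was unlikely to lower this median, and it does not decide on depth. Less cell RNA relative to background in control microvesicles could account for part of this pattern. Among 10000 lists matched on microvesicle abundance, the median cell level of the features called higher lay at percentile 100. It lay at 99.94 among lists matched on mean abundance over all libraries. For the 16 called lower these percentiles were 0.01 and 0.02. Cell libraries also entered the spread behind the calls, so cell level may have shaped which features were called, and matching does not remove this. Of the 53, 0 were called above construct cells, in a comparison that called 48% of simulated 16-fold changes, but 32 had a fitted value above them (median over the 53 of 0.40), such as AGO1 (38756 ± 30498 against 3919 ± 734 CPM), SF3B4 (8521 ± 3127 against 879 ± 337) and ZBTB7B (24362 ± 15178 against 7994 ± 1085). In control cultures 46 were called below cells (median -5.32), against 11.05 for independent lists and at most 22 for as many features in 20 simulations with unchanged microvesicles. Part of this excess may come from the shared control libraries. The simulations also used the spread shared with cells, which may be too small for microvesicles, so 22 may be too low. Loading of RNA by the YTHDF1 construct stays open, since these values do not exclude it. They also cannot tell it from that difference in background.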

How the results depend on the processing

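Chosen after seeing the data were the tests without the 2 most abundant features, on R1 or R2 alone, at equal depth, by position, and with the features of the main fit kept.

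The calls rested on few libraries and on a spread per feature estimated over cell and microvesicle libraries together. Cell libraries take no part in the contrast between microvesicles, yet leaving 1 out changed its calls, and without all 4 there were 0. The lowest and highest counts with 1 library left out were 0 and 115 for construct against control microvesicles, 0 and 123 for microvesicles against cells in construct cultures, 32 and 410 in control cultures, and 0 and 62 for the interaction; they were 0 for cells, symbol lists and construct genes. Leaving out a library also changed the filter, to between 1279 and 1874 features tested, and the lone library was assumed to vary like the others. For construct against control microvesicles (69), edgeR called 225 features unfiltered, 37 at a mean of at least 5 CPM and 0 with 4 libraries, DESeq2 called 141 and limma-voom 21. For construct cultures (58) the counts were 93 unfiltered, 33 at 5 CPM, 16 by library size, 0 with 4 libraries, 106 with DESeq2, and 34 at equal depth with the 2 most abundant features also left out. For control cultures (407), 269 were called at 5 CPM. For the interaction (20) they were 10 with upper-quartile factors, 61 unfiltered and 59 with DESeq2. With the 1113 features kept, leaving out a cell library gave 9, 9, 16 and 16 calls between microvesicles, 0 for construct cultures and the interaction, and 99 and 84 in control cultures without control cell library I or II. With 4 libraries and those features it gave 0 between microvesicles, 25 for construct cultures and 21 between cells.

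The replicate block gave 76, 374 and 21 calls for construct cultures, control cultures and the interaction, and changed no list. The median log2 fold change over features moved with scaling, from -0.24 to 0.41 by library size for construct against control microvesicles. By position 2 lists passed, and both calls were lost with an estimated correlation. The length trend (-0.215) was -0.0233 at 5 CPM, -0.255 given abundance, and between -0.257 and 0.0713 with 1 library left out. Over 20 trends, 24 of 160 values with a library left out and 5 of 35 others had the opposite sign. The microvesicle excess of the 100 most abundant features, 5.33 points, turned to -13.6 without the 2 dominant ones. The mean log2 fold change at ribosomal protein positions, 0.19 between microvesicles, reversed to -0.00136 on R1, -0.0126 without construct cell library II and -0.59 without construct microvesicle library II, where the interaction, 0.65, was -0.303. With 1 library left out these values reached 0.82 and 1.24, and none of the reversed ones passed the threshold. Leaving out mitochondrially encoded genes removed no counts and says nothing.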

Other observations

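The lists by position, including the one of ribosomal protein genes with pseudogenes, and the single genes compared by symbol and position were chosen after the values were seen.

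By GRCh38 position, 33 features of ribosomal protein genes and pseudogenes were tested in control microvesicles against cells: 9 were lower and 1 higher (5 adjusted over the list alone), with a mean log2 fold change of -1.50 (camera adjusted p = 0.0437; adjusted p = 0.576 with an estimated correlation). The endoplasmic reticulum stress list passed in the interaction (adjusted p = 0.0165; adjusted p = 0.285 with an estimated correlation) on 3 features at the positions of ATF3 and SESN2, of which 0 passed over all features (2 adjusted over the list alone).

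Single genes showed the same shift of reads. The symbol ILF2 had 1484 counts and the feature at its GRCh38 position 13453, EIF3I had 78 and 9329, and RPL11 had 7 and 7284. Exceptions were STMN1, with 908 and 95, ENO1, with 170 and 170, and RPL5, which had 0 features at its position.

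The 2 most abundant features kept a steady ratio in microvesicles: LINC01128 held 63.5% and 65.4% of their sum in construct and 64.1% and 65.1% in control libraries.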
